A study of Homo sapiens with 8 samples.

How the data were processed

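RNA was measured by paired-end sequencing of poly(A)-selected libraries in 8 samples of HCT116, an established human colorectal cancer cell line. The labels' RNA protocol speaks of an adipose type, which does not match a colorectal line, while the other labels name HCT116. Of 10 adipocyte markers 2 were above the filter, as were 3 of 22 intestinal differentiation genes and 6 of 12 hepatocyte markers. These counts therefore do not settle the tissue. Per the labels, 4 samples were controls and 4 had been exposed to hFGF19, human fibroblast growth factor 19, at 100 ng/ml for 72 hours. Nothing in the labels says whether the 4 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

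The values used were the FPKM values that the authors deposited, 1 per gene and sample (a gene's reads relative to the length of its model and to the reads of its library). HISAT2 2.0, StringTie 1.3.0 and the human build hg19 are named in the submitters' processing notes, without a role for each. The counting step, the annotation release, the strand setting and any filter are not given in the sources used here, so overlapping and antisense genes may share reads, as may paralogs and pseudogenes. The deposited table had 59641 genes with unique identifiers, of which 965 had no symbol and an identifier that is not an Ensembl one. All 8 value columns were matched to a sample by name. Genomic positions are not used here, since the table gives none and the reference used here is of another build than hg19.

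Low FPKM values of a gene were whole multiples of 1 step, which let the read number behind each value be worked out. With a gene length that was also whole, 99.963% of the values above 0 came out as whole reads within 0.02 reads. The steps gave totals per library between 17121190 and 20752753 reads, and the recovered reads added up to 99.97% of the total in each library. Nearly all of each total was thus reads counted to a gene. The median gene tested had 431 reads per library. PCR copies were not removed in a way known here, so read numbers are not numbers of independent molecules.

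The main comparison, hFGF19 minus control, was fitted with limma 3.58.1 in R 4.3.3 to log2(FPKM + 1), with a variance trend and a two-sided moderated test, over the 14100 genes with a mean of at least 1 FPKM across the 8 samples. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p below 0.05 was called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. A count of calls of at least 2-fold used a log2 change of 1 or more. Of 28 gene lists fixed beforehand, the 22 with at least 5 genes tested were compared with all other genes by camera, from limma, with a preset correlation of 0.01 between genes. Camera with a correlation estimated for each list, and the rotation test fry, were run as alternatives. Fry's directional test asks whether the genes of a list move on balance 1 way and does not compare them with other genes. Single values per sample were compared by an exact two-sided permutation test of the difference of means, whose smallest p with 4 against 4 samples is 0.029. A paired version, which flips the signs of the within-pair differences, was added after seeing the data. Principal components were taken from the centred log2 values of the genes tested.

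The lists covered the FGF receptor system, ERK pathway target and feedback genes, ETS family transcription factors, NF-kB target genes, mesenchymal genes, epithelial genes, matrix proteases and inhibitors, Wnt target genes, p53 target genes, interferon-stimulated genes, hypoxia response genes, heat shock genes, and unfolded protein and amino acid stress genes. They also covered cell cycle, glycolysis, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, mitochondrially encoded, ribosomal protein and replication-dependent histone genes, as well as bile acid and FXR genes and intestinal differentiation genes. Markers of hepatocytes, immune cells, fibroblasts, endothelial cells and adipocytes stood for other cell types.

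The design, the lists, the main alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and falls among called genes with a symbol and groups that did not overlap, or all of them where a direction had fewer. It added up to 4 called members of each list, and genes fixed by name: FGF19, KLB, FGFR1 to FGFR4, ELF4, SRC, RELA, NFKB1, NFKBIA, DUSP6, SPRY4, ETV4, ETV5, EGR1, CDH1, VIM, SNAI1, MMP2 and MMP9. Any other gene named was chosen after its values were seen.

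The labels give both groups the replicate numbers 1 to 4 without saying what a number stands for. The deviations from the group means of samples with the same number correlated across genes at 0.30, 0.17, 0.17 and 0.11, against -0.45 to 0.44 with a median of -0.17 between samples of different number and group, so that the highest of these lay above all 4. As each of the 4 correlations was above 0.1, the numbers were taken to pair the samples. This pairing comes from the data and not from a stated design. A fit with the replicate number as a block was run beside the main one. Chi-square values per degree of freedom between the reads of samples of the same group lay between 3.51 and 27.8. Between those of different groups they ran from 3.64 to 27.45, so no library was a copy of another. By these values the hFGF19 library nearest to control 1 had its own number (3.71). For control 2 it was number 3 (4.85 against 7.2 for number 2). For control 3 it was number 2 (3.71 against 9.2 for number 3), and for control 4 number 1 (3.64 against 8.18 for number 4). The pairing is therefore uncertain, and results by pair or with the block rest on it.

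Alternatives covered the pseudocount, the filter on low values, the scaling of the libraries, the block, weights per library, the variance model, and leaving out each library in turn. Added after seeing the data were limma voom on the recovered reads, fits on replicate numbers 1 and 4 alone or 2 and 3 alone, a blocked fit with each library corrected for GC content and gene length, and camera with both an estimated correlation and the block. GC content was taken from reference transcripts matched by gene identifier, for 98.8% of the genes tested.

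The fit was tested on simulated data drawn from the means and depths of these libraries, in 5 simulated sets with 200 changed genes each among the 14100. It recovered 14.2% of genes changed 1.25-fold, 66.4% of those changed 1.5-fold and 87.9% of those changed 2-fold. Of 69678 simulated values with no change, 40 were called. A list shifted 1.25-fold was called in 5 of 5 sets, with 0 calls of other lists. The simulated genes were drawn independently of each other and without differences between replicate numbers. In the data, the correlation estimated within a list was 0.133 for the NF-kB target genes and 0.895 for the ribosomal protein genes. The simulation therefore does not give the rate of false calls in data of this structure. Reads were recovered with Python 3.11.15 and numba 0.67.0, and plots were drawn with matplotlib 3.10.9.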

Results

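Gene expression was measured by RNA sequencing in HCT116 cells, a human colorectal cancer line, in 4 control samples and in 4 samples after 72 hours with 100 ng/ml hFGF19. FGF19 is a hormone of the fibroblast growth factor family that signals mainly through the receptor FGFR4 with its co-receptor KLB. The labels do not say for how long the controls were cultured. The FPKM values implied totals between 17121190 reads (hFGF19 replicate 2) and 20752753 reads (hFGF19 replicate 1). These are nearly all reads counted to a gene, and the number of other reads is not known. The totals did not differ detectably between the groups (exact permutation p = 0.83). The title of the series ties FGF19 to metastasis through FGFR4, ERK and NF-kB. The comparison of the groups therefore bears on which genes differed, and on whether genes of these pathways were among them.

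Cells exposed to hFGF19 had higher levels of a small set of genes, among them the chemokine genes CXCL1 and CXCL8 and the cytokine genes CSF3 and IL6. CXCL1 (ENSG00000163739), a chemokine that attracts neutrophils, rose from 291 ± 3.69 to 584 ± 45.8 FPKM, and CSF3 (ENSG00000108342), the granulocyte colony-stimulating factor, rose from 9.51 ± 1.22 to 20.6 ± 2.27 FPKM (mean ± SD, n = 4). CXCL8 (ENSG00000169429), another neutrophil chemokine, rose from 414 ± 33.7 to 685 ± 31.9 FPKM. The cytokine IL6 (ENSG00000136244) rose from 17.6 ± 1.44 to 29.8 ± 0.295 FPKM. LCN2 (ENSG00000148346), an iron-siderophore binding protein of epithelia and neutrophils, rose from 125 ± 11.3 to 206 ± 10.9 FPKM.

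In all, 15 of the 14100 genes tested changed at an adjusted p below 0.05 by limma, of which 14 rose and 1 fell. The log2 fold changes were 1.04 ± 0.0999 (SE) for CSF3, 1.0 ± 0.0602 for CXCL1, 0.73 ± 0.0652 for IL6, 0.73 ± 0.0658 for CXCL8 and 0.72 ± 0.0699 for LCN2. The adjusted p of these genes ranged from 0.000106 for CXCL1 to 0.00226 for CSF3 and LCN2 (limma, Benjamini-Hochberg). The chemokines CXCL3 and CXCL2 rose by log2 0.66 ± 0.0869 and 0.64 ± 0.0838, both with an adjusted p of 0.0186 by limma. PTGS2, the inducible cyclooxygenase, rose from 15.04 ± 0.675 to 23.4 ± 1.24 FPKM (adjusted p = 0.00230, limma). ZC3H12A, an RNase that degrades mRNAs of inflammatory genes, rose from 52.8 ± 3.58 to 78.5 ± 7.33 FPKM (adjusted p = 0.0247, limma). SAA1, an acute-phase protein with near-identical paralogs, rose from 1.17 ± 0.261 to 2.79 ± 0.280 FPKM on 53 reads in the controls and 126 with hFGF19 (adjusted p = 0.0430, limma).

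The remaining rises were of IER3, an early response gene, from 181 ± 6.07 to 235 ± 11.6 FPKM, and of 3 genes outside the naming rule. CXCL5, a neutrophil chemokine, was at 116 ± 6.34 and 170 ± 6.73 FPKM, and PDZK1IP1, a small membrane protein, at 33.1 ± 1.67 and 44.6 ± 0.920 FPKM. FTLP2 is a pseudogene of the ferritin light chain and may take reads of FTL. It was at 4.27 ± 0.201 and 6.48 ± 0.395 FPKM. The gene that fell was AC144568.1 (ENSG00000253620), a short gene model of 137 bases, which went from 3.43 ± 1.254 to 0.585 ± 0.209 FPKM on 35 and 6 reads.

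The 4 hFGF19 libraries lay on 1 side of the 4 control libraries in all 15 genes, so that every way of pairing them gives the same direction. In pairs of samples with the same replicate number, the log2 changes of CXCL1 were 1.09, 0.99, 0.86 and 1.06, and those of CSF3 were 0.97, 1.22, 0.97 and 0.99. Over all genes tested, 440 had groups that did not overlap, which was 3.1% against 2.9% by chance. At an unadjusted p below 0.05 by limma there were 596 genes, fewer than the 705 that chance alone would give. On the log2(FPKM + 1) scale, a change of at least 2-fold with an adjusted p below 0.05 was reached by CSF3 and AC144568.1. That scale understates the change of low genes such as SAA1 (1.17 and 2.79 FPKM, log2 change 0.81). CXCL1 lay just under that size, and just above it with a pseudocount of 0.1 or 0.5, which gave 3 genes.

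**Figure D1:**
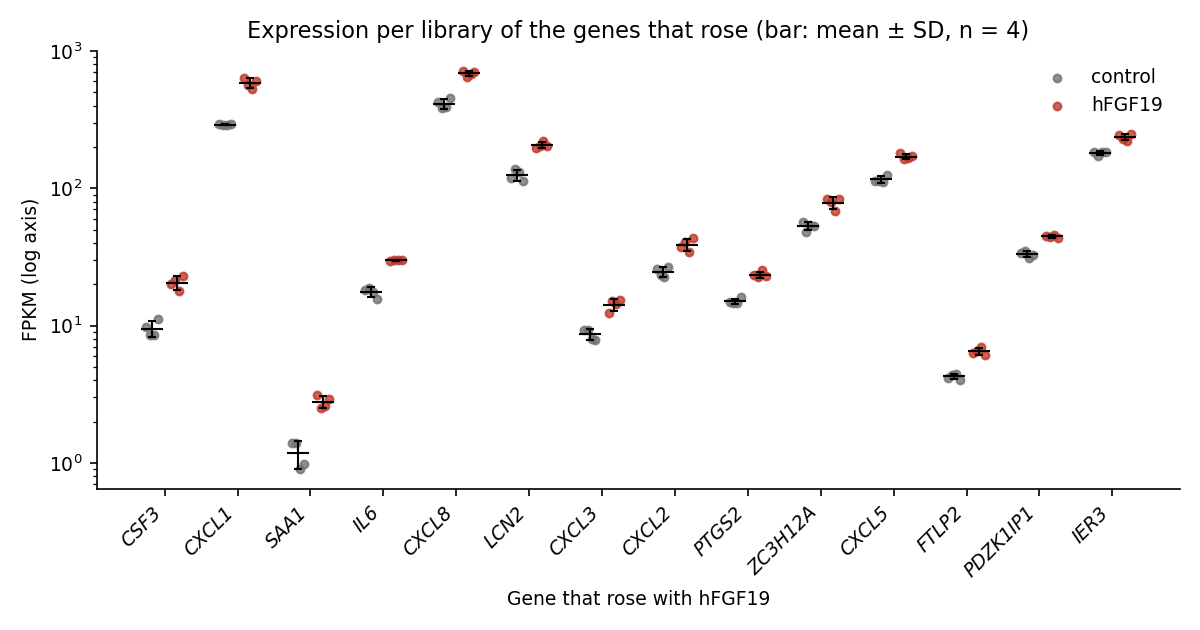
FPKM on a log axis in each of the 8 libraries for the 14 genes that rose, with grey points for control, red points for hFGF19 and black bars for the mean ± SD (n = 4). In each gene all 4 hFGF19 libraries lie above all 4 controls, as for CXCL1 with means of 291 and 584 FPKM.

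With the replicate number as a block, 21 genes changed, 18 up and 3 down, and 13 of them were among the 15 above. SAA1 (adjusted p = 0.0557) and FTLP2 (adjusted p = 0.0561) were no longer called by limma in that fit. Among the genes that the block added, chosen after their values were seen, the complement component C3 was at 487 ± 47.6 and 708 ± 81.2 FPKM (blocked adjusted p = 0.00310, limma). The monocyte chemokine CCL2 was at 25.6 ± 2.92 and 38.1 ± 3.51 FPKM (blocked adjusted p = 0.00337, limma). The mitochondrial superoxide dismutase SOD2 was at 159 ± 23.7 and 212 ± 30.4 FPKM (blocked adjusted p = 0.0141, limma). CXCL1, IL6, CXCL8, CSF3, LCN2, PTGS2 and CXCL5 were called in each of the 8 fits that left out 1 library, whereas SAA1 and FTLP2 were called in 0 of them. The called genes AC144568.1, CXCL2, CXCL3, PDZK1IP1, IER3 and ZC3H12A were called in 1 to 3 of these fits.

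The NF-kB target genes stood above the other genes as a group. Of 30 members tested, 7 rose, namely CXCL1, IL6, CXCL8, CXCL3, CXCL2, PTGS2 and CXCL5, 0 fell and 23 did not pass. With the block 10 rose, the others, named after their values were seen, being CCL20, CSF2 and SOD2 (blocked adjusted p of 0.0168, 0.0359 and 0.0141, limma). Adjusted over the list alone, 13 rose, among them NFKBIA, which encodes an inhibitor of NF-kB (135 ± 5.39 and 150 ± 6.05 FPKM). The adjusted p of NFKBIA over all genes was 0.9998 by limma. The list had a median log2 change of 0.17 and an adjusted p of 4.60e-27 by camera with the preset correlation. It held with an adjusted p = 0.0143 with an estimated correlation, and an adjusted p = 0.00449 by fry. With both the block and an estimated correlation the adjusted p was 0.0503. NFKB1, a subunit of the factor itself, was at 37.1 ± 4.19 and 38.0 ± 3.01 FPKM, and RELA at 120 ± 14.2 and 117 ± 16.7 FPKM, and neither passed the test (adjusted p = 0.9998 each, limma).

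**Figure D2:**
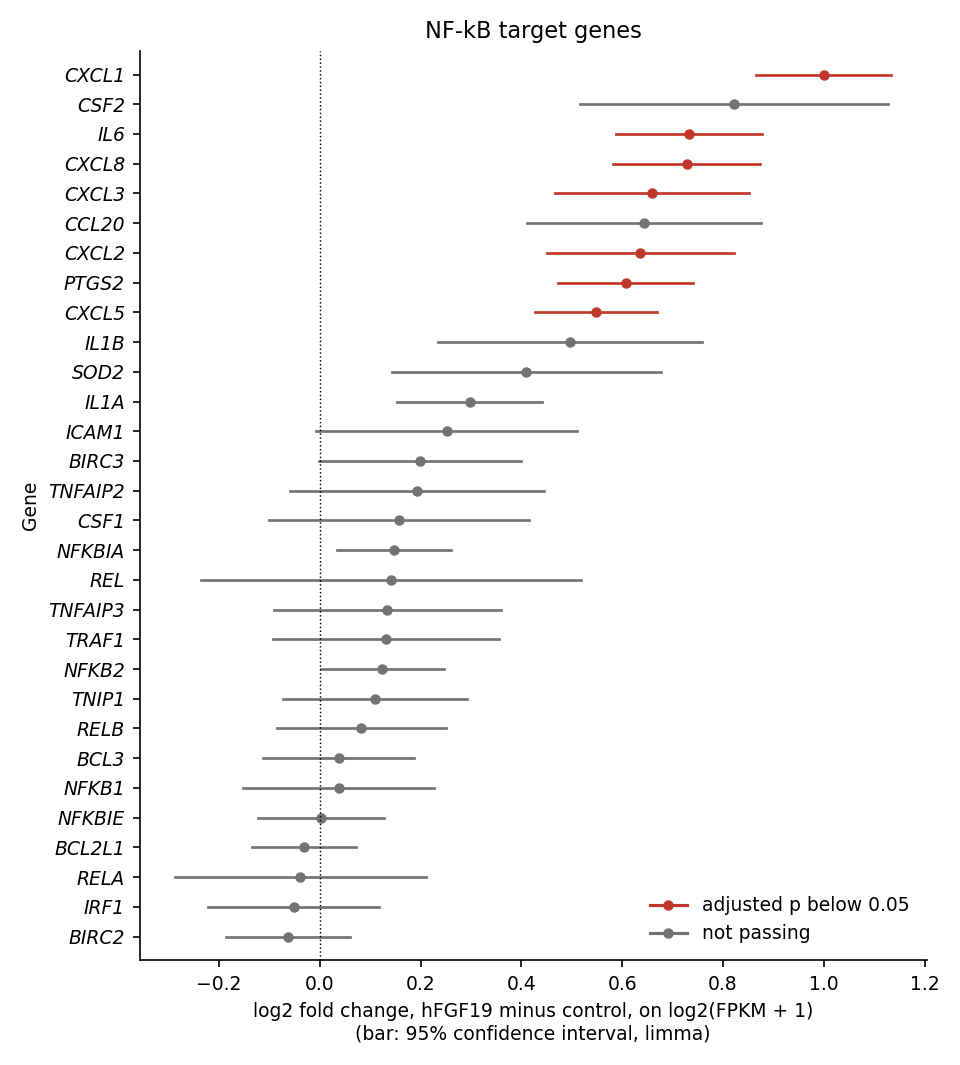
Log2 fold change, hFGF19 minus control, of the 30 NF-kB target genes tested, with bars for the 95% confidence interval (limma) and red for an adjusted p below 0.05 over all genes, all without the block. CXCL1 stands highest at 1.0, and RELA lies at -0.04 in the lower part.

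The FGF receptors were expressed, whereas the co-receptor KLB was close to the limit of detection. FGFR4 (ENSG00000160867) was at 51.4 ± 2.32 FPKM in controls and 44.9 ± 5.51 with hFGF19, with groups that overlapped. It was lower in 4 of 4 pairs, as was FGFR2, whose groups overlapped too. The log2 change of FGFR4, -0.20 ± 0.0825, did not pass (adjusted p = 0.9998, limma). FGFR2 was at 25.3 ± 2.60 and 21.8 ± 2.50 FPKM, FGFR1 at 154 ± 11.4 and 143 ± 11.7, and FGFR3 at 8.07 ± 0.251 and 7.41 ± 0.834, none of which passed. KLB was at 0.0494 ± 0.0289 and 0.0655 ± 0.0229 FPKM, on 22 and 29 reads over 4 libraries each, and a difference was not detectable at this depth (exact permutation p = 0.457). Endogenous FGF19 mRNA was at 0.191 ± 0.107 and 0.168 ± 0.0520 FPKM, on 35 and 31 reads (exact permutation p = 0.714). Of the 14 genes of the FGF receptor system tested, 0 passed, and the list was not called (adjusted p = 0.131, camera).

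Among the ERK pathway target and feedback genes, IER3 rose, with a log2 change of 0.38 ± 0.0523, and 23 of 24 genes did not pass. Adjusted over the list alone, 1 gene rose. The list was called higher by camera (adjusted p = 0.0239) but not with an estimated correlation between its genes (adjusted p = 0.461 with an estimated correlation). DUSP6, which encodes a phosphatase that ERK induces as feedback, had a log2 change of 0.03 with a 95% confidence interval of -0.14 to 0.20. The changes of SPRY4, a feedback inhibitor, and of the ETS factors ETV4 and ETV5 were 0.09 ± 0.0881, 0.16 ± 0.0572 and 0.05 ± 0.120, and that of the early gene EGR1 was -0.08 ± 0.144. None of these passed (adjusted p = 0.9998 each, limma). The ETS family transcription factors were not called as a list (adjusted p = 0.975, camera), with a median of -0.02 and a mean of -0.01. Camera, which compares a list with the other genes, gave an upward direction, and the median log2 change of all genes was -0.0132. ELF4, a member of that family, was at 33.9 ± 3.89 and 34.3 ± 4.78 FPKM and changed sign with scaling to TPM. The kinase gene SRC was at 89.7 ± 9.75 and 95.2 ± 10.1 FPKM and did not pass.

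**Figure D3:**
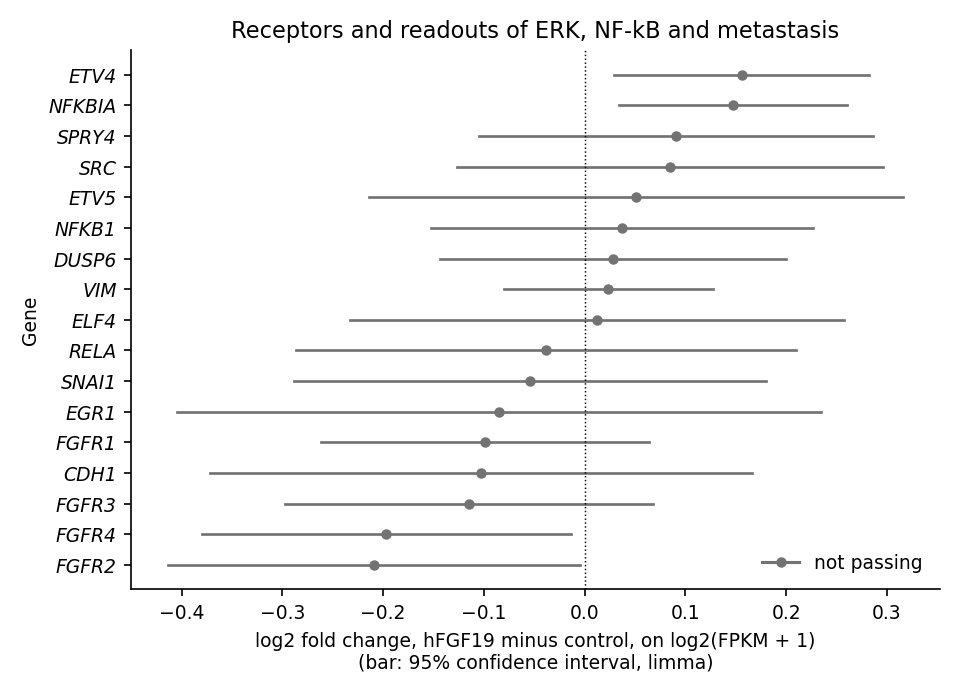
Log2 fold change, hFGF19 minus control, of the genes fixed by name that were tested, with bars for the 95% confidence interval (limma). No gene has an adjusted p below 0.05, and the changes run from -0.21 for FGFR2 to 0.16 for ETV4.

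Epithelial and mesenchymal genes showed no called change after 72 hours. CDH1, the epithelial cadherin, was at 42.0 ± 6.31 and 39.0 ± 5.63 FPKM, the intermediate filament gene VIM at 229 ± 6.53 and 233 ± 7.21, and the transcription factor SNAI1 at 1.63 ± 0.184 and 1.52 ± 0.0474. The log2 change of VIM had a 95% confidence interval of -0.08 to 0.13. Of 17 epithelial and 19 mesenchymal genes tested, 0 passed, with adjusted p of 0.528 and 0.417 for the lists (camera). The gelatinases MMP2 and MMP9 had 18 and 7 reads in the controls and 18 and 15 with hFGF19, too few to detect a difference (exact permutation p = 1 and 0.4). Of the 18 matrix proteases and inhibitors tested, 0 passed over all genes and 1 rose adjusted over the list alone. That gene was MMP7, named after its values were seen, a protease of epithelia at 2.94 and 5.30 FPKM (log2 change 0.67 ± 0.125, adjusted p over all genes = 0.153, limma). The list was called higher (adjusted p = 0.0332, camera), but the adjusted p = 0.422 with an estimated correlation, and 0.0709 with the block.

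Hepatocyte markers, included to detect RNA of another cell type, were higher as a list. All 6 members tested had higher means with hFGF19, 0 passed over all genes, and 3 rose adjusted over the list alone. These were the fibrinogen chains, named after their values were seen, which are products of the liver and of the acute-phase response. FGB was at 14.1 and 19.5 FPKM (log2 change 0.43 ± 0.0796), FGG at 9.15 and 13.3 (0.49 ± 0.112) and FGA at 2.93 and 3.76 (0.27 ± 0.0939). The list had an adjusted p of 3.58e-07 by camera and an adjusted p = 0.0143 with an estimated correlation, and 0.00464 by fry. With both the block and an estimated correlation the adjusted p was 0.172, and with the block it was 0.0738 by fry. ALB, an abundant mRNA of hepatocytes, was at 3.74 ± 0.593 and 4.21 ± 0.382 FPKM, and APOA1 was at 0.0660 ± 0.0294 and 0.0255 ± 0.0296 FPKM.

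Genes of the ribosome and of mitochondrial respiration had slightly higher means. All 34 ribosomal protein genes were higher with hFGF19, or 29 after quantile normalization, and 0 of them passed. Their median log2 change was 0.09, or 0.04 after quantile normalization, with an adjusted p of 1.33e-06 by camera, but the adjusted p = 0.499 with an estimated correlation. Without the library hFGF19 replicate 3 it was 0.0669. Ribosomal protein genes share reads with many pseudogenes, and their share of all FPKM was 8.46% ± 0.606 in controls and 8.92% ± 0.848 with hFGF19 (n = 4, exact permutation p = 0.4). That share was higher with hFGF19 in 4 of 4 pairs of the same replicate number (exact paired permutation p = 0.125, the smallest that 4 pairs allow, or 0.625 adjusted over 5 measures). Of 26 oxidative phosphorylation genes, 22 were higher and 0 passed (adjusted p = 0.000719 by camera). For that list the adjusted p = 0.460 with an estimated correlation, and it was 0.126 without hFGF19 replicate 3. Of 13 mitochondrially encoded genes, 10 were higher (median log2 change 0.08), or 8 after quantile normalization (median 0.02), and 0 passed (adjusted p = 0.0462 by camera). Their adjusted p = 0.422 with an estimated correlation, and they held 7.89% ± 0.387 and 8.04% ± 0.135 of all FPKM (n = 4, exact permutation p = 0.486), higher in 2 of 4 pairs. Thus 7 of 22 lists were called higher and 0 lower with the preset correlation. Without the block, the NF-kB and hepatocyte lists were the 2 that held with an estimated correlation or with fry. With the block, 0 lists held with an estimated correlation, and 1, the NF-kB list, held by fry.

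The metabolic lists other than oxidative phosphorylation, and the growth and stress lists, were not called. The cell cycle genes came nearest to a call, with 32 tested, 21 higher and an adjusted p of 0.0531 by camera. The adjusted p was 0.0999 for 16 heat shock genes, 0.111 for 23 glycolysis genes and 0.171 for 9 replication-dependent histone genes. It was 0.291 for 15 Wnt target genes and 0.417 for 24 cholesterol synthesis genes. It was 0.556 for 15 fatty acid synthesis genes, and 0.528 for 26 unfolded protein and amino acid stress genes. It was 0.195 for 23 interferon-stimulated genes. The 20 hypoxia response genes had an adjusted p of 0.164, with a median of -0.01 but a mean of 0.02 and an upward direction by camera. Adjusted over the list alone, 1 hypoxia gene rose, ANKRD37, at 3.21 and 4.45 FPKM. The 22 p53 target genes had an adjusted p of 0.319. Adjusted over the list alone, 1 of them rose, the stress cytokine GDF15, at 975 and 1170 FPKM. Both were named after their values were seen, with adjusted p over all genes of 0.438 and 0.461 (limma).

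The other 6 lists had fewer than 5 genes above the filter and were not tested. All their genes were in the data, most of them below the filter. Of 13 bile acid and FXR genes 3 were above it, among them the bile acid receptor gene NR1H4 at 39.1 and 40.5 FPKM. Of 22 intestinal differentiation genes 3 were above the filter. So were 2 of 16 immune, 2 of 10 endothelial and 2 of 10 adipocyte markers, and 1 of 12 fibroblast markers. No member of the 6 lists passed over all genes or adjusted over its list alone.

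The largest variation between libraries did not follow the treatment. The first principal component held 35.4% of the variance, and its group means did not differ (exact permutation p = 0.857). Libraries with replicate numbers 1 and 4 had scores between -14.9 and -5.88, and those with numbers 2 and 3 between 6.73 and 18.2, in both groups. The second component held 13.2% of the variance (exact permutation p = 0.086).

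**Figure D4:**
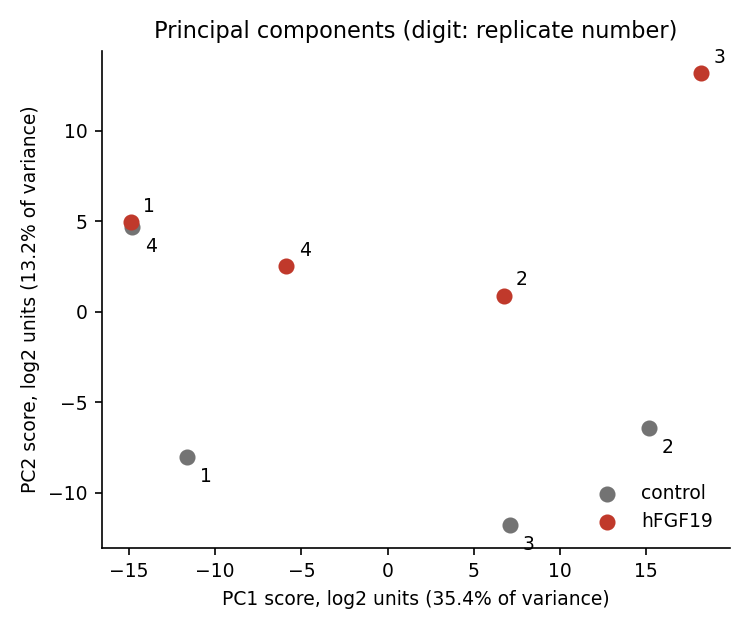
Scores of the 8 libraries on the first and second principal component of log2(FPKM + 1), in log2 units, with grey for control, red for hFGF19 and a digit for the replicate number. Numbers 1 and 4 lie on the left, with scores up to -5.88, and numbers 2 and 3 on the right, from 6.73, in both groups.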

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

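In 3 of the 76 groups of 4 libraries examined, 1 library lay apart from the other 3 by more than Dixon's 95% critical value for the gap divided by the range. Chance alone would give about 3.8 such groups. For PTGS2, control 4 was at 16.1 FPKM and the other controls at 14.7 FPKM (ratio 0.938), and all 4 hFGF19 libraries stood higher, from 22.5 to 25.2 FPKM. For IER3, control 2 was at 172 FPKM and the other controls at 183 to 184 FPKM (ratio 0.916). For SRC, hFGF19 3 was at 80.1 FPKM and the other hFGF19 libraries at 98.9 to 101 FPKM (ratio 0.892). These 3 values came from 3 different libraries, and no explanation of them was tested.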

How the results depend on the processing

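The fits by voom, on subsets of replicate numbers, with a GC and length correction, and with the block and an estimated correlation together were chosen after seeing the data. No gene or list reversed where it was called. Not called, DUSP6, EGR1, ELF4, ETV5, NFKB1 and RELA changed sign under some alternative, as did the medians of the epithelial, p53, hypoxia and unfolded protein lists with scaling. The count of 15 changed genes stayed between 10 and 21 over the other alternatives that kept all 8 libraries (voom on recovered reads gave 14, with 12 shared). It was 8 with replicate numbers 1 and 4 alone and 9 with 2 and 3 alone, where 2 libraries were left per group, and 7 to 13 when 1 library was left out. It was 7 without control 1, hFGF19 2 or hFGF19 4, 8 without control 3 and 9 without hFGF19 1, with fewer samples in each. The count of at least 2-fold, 2 genes, was 1 with a filter of 5 FPKM, which removes AC144568.1, 1 without a filter, 1 with numbers 1 and 4 alone, and 5 with numbers 2 and 3 alone. It was 3, with CXCL1 added, for a pseudocount of 0.1 or 0.5, median-ratio scaling or array weights, and 3 by voom, without AC144568.1. It was 0 to 3 when 1 library was left out: 0 without hFGF19 4, and 1 without control 3 or hFGF19 1. Beyond fewer samples or genes, the cause was not tested. Of the 15 called genes, AC144568.1, CXCL2, CXCL3, PDZK1IP1, IER3 and ZC3H12A were called in 1 to 3 of the 8 fits without 1 library.

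The count of 7 moved lists was 4 with a filter of 0.1 FPKM, 4 after quantile normalization, and 4 with numbers 1 and 4 alone. It was 2 with an estimated correlation, 2 by fry, and 0 with an estimated correlation and the block. It was 4 to 11 when 1 library was left out: 4 without control 2, control 3, hFGF19 1 or hFGF19 4, and 11 without control 4. The cause of these changes was not tested. The NF-kB list was called in each alternative except the estimated correlation with the block. The hepatocyte list was called wherever it was tested except in that fit and by fry with the block (0.0738), and the 5 FPKM filter left it under 5 genes. Their adjusted p ranged from 3.11e-32 to 0.0503 and from 7.99e-08 to 0.172. The cell cycle list passed with 8 alternatives, for example at 0.0425 after median-ratio scaling (range 0.00151 to 0.596). Other uncalled lists that passed: heat shock without control 4 (0.00422) and with numbers 2 and 3 alone (0.0161), glycolysis without control 4 (0.0373), hypoxia without control 4 (0.0373) or hFGF19 2 (0.0382), histones with numbers 1 and 4 alone (0.0312), and the FGF receptor system with 2 and 3 alone (0.0493). The blocked fit gave 21 genes, 3 of them at least 2-fold, and 6 lists. Beyond the calls given for it in the report, it added AKR1B1, RF00019 and MIR7856 (named after their values were seen) and changed no other call. Of the comparisons of single named genes, 621 kept their side of the threshold, 71 lost it and 0 gained it. Of those of single lists, 527 kept it, 51 lost it and 15 gained it.

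The median log2 change of all genes was between -0.0259 and -0.0028 over the scalings. The separation of the groups on the first component stayed without a call, at p = 0.857 with the 1000 most variable genes and 0.771 with a pseudocount of 0.1 (exact permutation). Depth limits genes such as KLB, FGF19, MMP2 and MMP9, with at most 35 reads per group. A count model was planned only for deposited read counts and was not run, as the deposited values are FPKM. To the recovered reads voom was applied instead. Gene identifiers were unique, so no rows were merged. Among the genes tested, 6 symbols belonged to more than 1 identifier, and these were kept as separate genes.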

Other observations

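The tests on the counts of changed genes, scaling, shuffled GC content, and the split of numbers 1 and 4 against 2 and 3 were chosen only after the result was seen. The NF-kB list was also grouped by kind of protein after its values were seen, so these groups are described without a test. Of 11 chemokines and cytokines tested, 6 rose (8 with the block) and the median log2 change was 0.64, while of 13 proteins of the pathway itself, such as its subunits and inhibitors, 0 rose with or without the block and the median was 0.11.

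The rise of the called genes could come from RNA of other cells or from scaling. RNA of immune cells is argued against, as 6 abundant leukocyte genes (PTPRC, TYROBP, FCER1G, CD14, LYZ and CD68) were higher in sum by 0.046% of the summed rise of 847 FPKM of the called genes. The highest of them, CD14, was at 0.935 and 1.45 FPKM. None of the scalings tried removed the rises, as the lowest log2 change of the 14 risers was 0.365 or more under each. The scalings differed little, with a median log2 change of all genes between -0.0259 and -0.0028, so they could hardly have done so. Of the 14, 13 were still called after quantile normalization and 12 with TPM. Each group held all 4 replicate numbers, and with these as a block 13 of the 15 genes were called. RNA of cells other than immune cells was not tested for these genes and stays open. So does any difference in handling between the groups other than hFGF19, such as vehicle or culture time, which the labels do not give. A response to hFGF19 remains a hypothesis.

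Chance cannot be excluded from the count of splits over all 35 ways to part the 8 libraries, since 2 of them gave as many genes as the real 15. The other was numbers 1 and 4 against 2 and 3, with 2740 genes, which points to a structure of the samples. Genes changed at least 2-fold were as many in 2 of 35 splits (2 in the real one, 18 in the highest other), and moved lists in 3 of 35 (7 in the real one, 7 in the highest other). The 8 splits that part all 4 pairs are too few for a share under 0.05. Among them the real split called 15 genes and the highest other 0, or 21 and 1 with the block, and for lists 7 and 5.

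The structure along the replicate numbers was larger than that of the treatment, and no biological explanation of it was tested. Gene length as its whole cause is argued against. Before removal of each library's length trend 302 genes differed between the 4 numbers, and after it 219 did. For GC content, a test written before its result was seen left 0 of the 302, which is what GC as the cause would give. With 20 trends of the same form on shuffled GC, 251 to 282 genes differed, so GC content may contribute to these differences. The calls had lain near the threshold (lowest adjusted p 0.0261, median 0.0380, and 0.0629 the lowest after correction), and the median range of their number means went only from 0.497 (SD 0.348) to 0.441 (SD 0.369) on the log2 scale, so the calls ended with little change in size. For numbers 1 and 4 against 2 and 3, 2854 genes were called after the GC trend was removed and 2426 after the length trend, against 2740 before, which argues against either as the whole cause of that part, and differences in library preparation or culture, which may underlie it, were not tested.

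The hepatocyte list could be higher through RNA of hepatocytes or through a wider rise of acute-phase genes. Hepatocyte RNA is argued against, as ALB, APOA1 and TTR, abundant in these cells, were higher in sum by 8.12% (SE 6.7) of the rise of FGB. Of the acute-phase genes outside the lists, 10 were tested as a set, with 7 higher, 3 lower, a median log2 change of 0.05 and 0 called, and camera gave p = 0.0172 with an estimated correlation. Among them C1S was at 5.13 and 6.84 FPKM and CRP at 24.2 and 30.4 FPKM, with adjusted p of 0.652 and 0.839 by limma, whereas C4BPA, HPX and SOCS3 were the 3 lower ones, SOCS3 at 48.5 and 46.7 FPKM. A mild acute-phase pattern may be present in part of these genes, as a hypothesis found and tested on the same data.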
